A study of Mus musculus with 2 samples.

How the data were processed

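H3K27me3, trimethylation of histone H3 at lysine 27, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in sciatic nerve of male C57/BL6 mice aged 8 weeks. The series holds 1 ChIP library and 1 input library, the sonicated chromatin set aside before immunoprecipitation. Per the labels' protocols, nerve was minced and crosslinked in 1% formaldehyde for 10 min, chromatin was sonicated to an average of 0.5 to 2 kb, and 300 µg of chromatin was incubated with 5 µg of antibody, with a 10% aliquot kept as input. The number of animals behind each library, the number of sequenced reads and the read length are not given in the sources used here. The nerve was not sorted into cell types, as far as the labels' protocols say.

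Per the submitters' processing notes, Bowtie was used and the genome build was mm10. The Bowtie version, the peak caller, its threshold and the use made of the input in the calling are not given in the sources used here. The deposited values are 1 list of peaks, each with a chromosome, a start, an end and a score that the authors' processing gave it. The meaning of the score is not given in the sources used here. All but 1 of the scores (99.98%) lay within 0.05 of a whole multiple of 2.5735, so each score was divided by 2.5735 and read as a number of reads. The lowest score, 25.7, then stands for 10 reads. If scores were scaled to 10000000 reads, which is an assumption, the ChIP library held about 3886000 reads. No read number of the input can be recovered from the peak list, and input values were not analysed here.

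Depth sets the precision of each peak. A peak of 10 reads has an exact 95% Poisson interval of 4.795 to 18.39 reads, a relative counting error of 31.62%. All intervals given for reads, peaks and shares cover counting error only and say nothing about variation between animals. With 1 ChIP library there are no replicates, so no p-values were computed. Random lists and shifted peaks describe this library.

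Genes came from a RefSeq table of assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on the chromosomes of the peak list. The table gives the start and end of each gene and no strand, transcripts or exons. A gene was called marked when a peak overlapped, by at least 1 bp, the 2 kb on each side of either annotated gene end. The plan made before the data were examined used the 5′ end alone. A peak at the 3′ end of a gene or in a neighbour's promoter therefore also counts. Reads given as near gene ends are all reads of the peaks that overlap these 2 kb windows, including reads that lie outside them. The planned split into exons and introns, the windows at every transcript start and the CpG content of marked genes were not run, because they need a transcript annotation or a genome sequence, which were not used here. Shares of a chromosome refer to its annotated span, from the start of its first gene to the end of its last. Peak positions are 1-based on mm10.

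The count of marked genes was set beside 1000 circular shifts of all peaks along their own chromosomes, starting at 3 Mb, which keep peak widths and clustering. The 33 gene lists were written before the data were examined. Each list's marked members were set beside 10000 random lists of the same size drawn without replacement from all protein-coding genes. A list was called above (or below) random lists when at most 10 of the 10000 reached as many (or as few) marked members. Shares carry exact Clopper-Pearson 95% intervals. For a share of 0, the largest share that the count allows was taken as 3 counts of the total. Neighbouring genes can share a peak and some genes sit in more than 1 list, so members and lists are not independent. Of the 40 nerve injury and repair genes, 7 (Shh, Gdnf, Olig1, Fgf5, Igfbp2, Runx2 and Cdkn2a) were known beforehand from work on Polycomb in Schwann cells.

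The genes named in the text were chosen by a rule set before the data were examined. It takes every marked repair gene, up to 8 unmarked ones, 8 set myelin genes and every other marked myelin gene. For each other list called above or below, it takes the 3 members with the most covered bases near their ends. It also takes the 10 widest domains, which are peaks merged within 5 kb, and the 4 Hox clusters. Some genes that the rule takes are not reported here. Genes outside this rule were chosen after their values were seen and are marked as such in the text.

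Settings varied, as set before the data were examined, were windows of 1 and 5 kb, the whole gene with 2 kb flanks, a window at least 50% covered, the 3061 peaks at or above the median score of 36.0, a background without olfactory and vomeronasal receptor genes, random lists matched on 10 classes of gene length, circular shifts in place of random lists, autosomes only, and the repair list without its 7 known genes. Settings added after seeing the data were peaks of at least 20 reads, the removal of 24 peaks with over 52.42 reads per kb (2.5 times the median), and each peak counted for its nearest gene only. The 24 peaks were also compared with the 100 other peaks closest in width to each, ties included. The search of families by symbol prefix, the counts over other gene types and the grouping of Hox genes by paralog number were also added after seeing the data.

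Counting was tested on simulated data. All 200 simulated genes with a peak were recovered among 21887 genes, with 0 differing from a direct count. Over 100 shifted peak sets, 17 of 3300 list tests (0.515%) were called, more than a limit of 10 in 10000 on each side would give for independent genes. Shifted peaks mark fewer genes (417.2 on average over 1000 shifts, against 1879), so this share is not the false-call rate of the lists reported here. Simulated lists of 40 genes were called in 16% of draws at a true share of 20%, in 42% at 25% and in 87% at 35%. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.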

Results

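The series maps H3K27me3, the histone mark laid down by the Polycomb repressive complex, in intact sciatic nerve, a tissue made largely of Schwann cells, fibroblasts, vessels, immune cells and the axons of distant neurons. There was 1 ChIP library and 1 input library from male mice aged 8 weeks, without replicates. Every value below therefore describes this 1 nerve preparation, and no difference could be set against variation between animals. The deposited peak list held 6018 peaks covering 7.61 Mb. The authors' score per peak, read as whole reads, gave a median of 14 reads per peak and 185225 reads in all peaks. At this depth 2209 peaks (36.71%) held 11 reads or fewer. Relative counting error is therefore larger for single narrow peaks than for broad regions with many reads.

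H3K27me3 in the nerve lay in many narrow peaks and in a smaller number of broad domains, the widest of them over Hox genes. The median peak was 643 bp wide (quartiles 500 and 1299 bp), and 2505 peaks (41.63%) had the shortest width in the list, 500 bp. The 204 peaks over 5 kb held 22.59% of all covered bases. Merging peaks within 5 kb gave 3818 domains, of which 282 exceeded 10 kb. Of the 10 widest domains, 5 overlapped Hox genes, the homeobox genes that set position along the body axis. The widest overlapped Hoxc9 to Hoxc13 (chromosome 15, 102900217 to 102982472, mm10), at 82256 bp with 24 peaks and 1124 reads. It was followed by a domain over Hoxa5 to Hoxa13 that also overlapped part of Hoxa3 (78857 bp), one over Evx2 and Hoxd8 to Hoxd13 that reached into Hoxd3 (68993 bp), Zic1 and Zic4 (57281 bp) and Hoxb5 to Hoxb9 (54362 bp). The remaining 5 lay over Lhx2 (48474 bp), Cyp26b1, which encodes a retinoic acid-degrading enzyme (48018 bp), Ttll6 and Hoxb13 (47525 bp), Pax7 (44935 bp) and Nkx2-3 (44016 bp).

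Of 21887 protein-coding genes, 1879 were marked, meaning that a peak lay within 2 kb of an annotated end (8.585%, exact 95% interval 8.217 to 8.964). Circular shifts of the same peaks marked 417.2 genes on average, with a central 95% range of 357 to 482 and a highest count of 538, so the observed count was 4.5 times the shifted mean. This ratio was 3.17 with a window of 5 kb and 1.81 when the whole gene and its 2 kb flanks were counted. Covered bases were concentrated in the same places. Within 2 kb of gene ends lay 38.4% of covered bases against 5.53% of the annotated span, while 27.8% lay elsewhere inside genes and 33.8% outside them. The share near gene ends was higher among peaks with more reads, which are also wider. Of peaks with 10 to 11 reads, 23.3% lay near a gene end, against 6.81% of shifted peaks. Of peaks with 50 reads or more, 61.7% did, against 11.3%.

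Transcription factors of embryonic lineages carried the mark at most of their genes. Of 64 neural lineage factors, 62 were marked (96.9%, 89.16 to 99.62), against 5.5 in the average random list and 15 in the highest. Lbx1 lay inside a peak of 23306 bp with 628 reads (chromosome 19, 45221383 to 45244688), En1 inside one of 15203 bp and Neurod2 inside one of 11705 bp. Of 57 mesoderm and endoderm factors, 50 were marked (87.7%), among them the heart regulator Nkx2-5 (17331 bp, 530 reads), Nkx2-3 (10226 bp) and Barx1 (15688 bp). Of 20 neural crest factors, 15 were marked (75%, 50.9 to 91.34), including Msx1, Zic1 and Tfap2a, whose widest peak spanned 18190 bp. No random list reached any of these counts. Among marked members, the median reads in peaks near gene ends were 230 for the neural list and 173 for the mesoderm and endoderm list, against 25 over all marked genes.

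The families to which many of these factors belong were also marked more often than random lists. Of 12 genes of the Irx and sine oculis homeobox families, 11 were marked (91.7%), with Irx1, Irx3 and Irx5 covered over 100% of their length. Marked members numbered 9 of 13 in the Tbx family (69.2%), including Tbx1, Tbx3 and Tbx5, and 13 of 19 in the Sox family (68.4%), including Sox1, Sox14 and Sox21. In the Fox family, 24 of 44 were marked (54.5%), and Foxa1, Foxa2 and Foxf1 had the most covered bases. No random list reached any of these counts. The lists overlap, since 4 of the Irx and sine oculis homeobox genes, 6 Sox, 7 Tbx and 6 Fox genes also stand in another list.

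**Figure D1:**
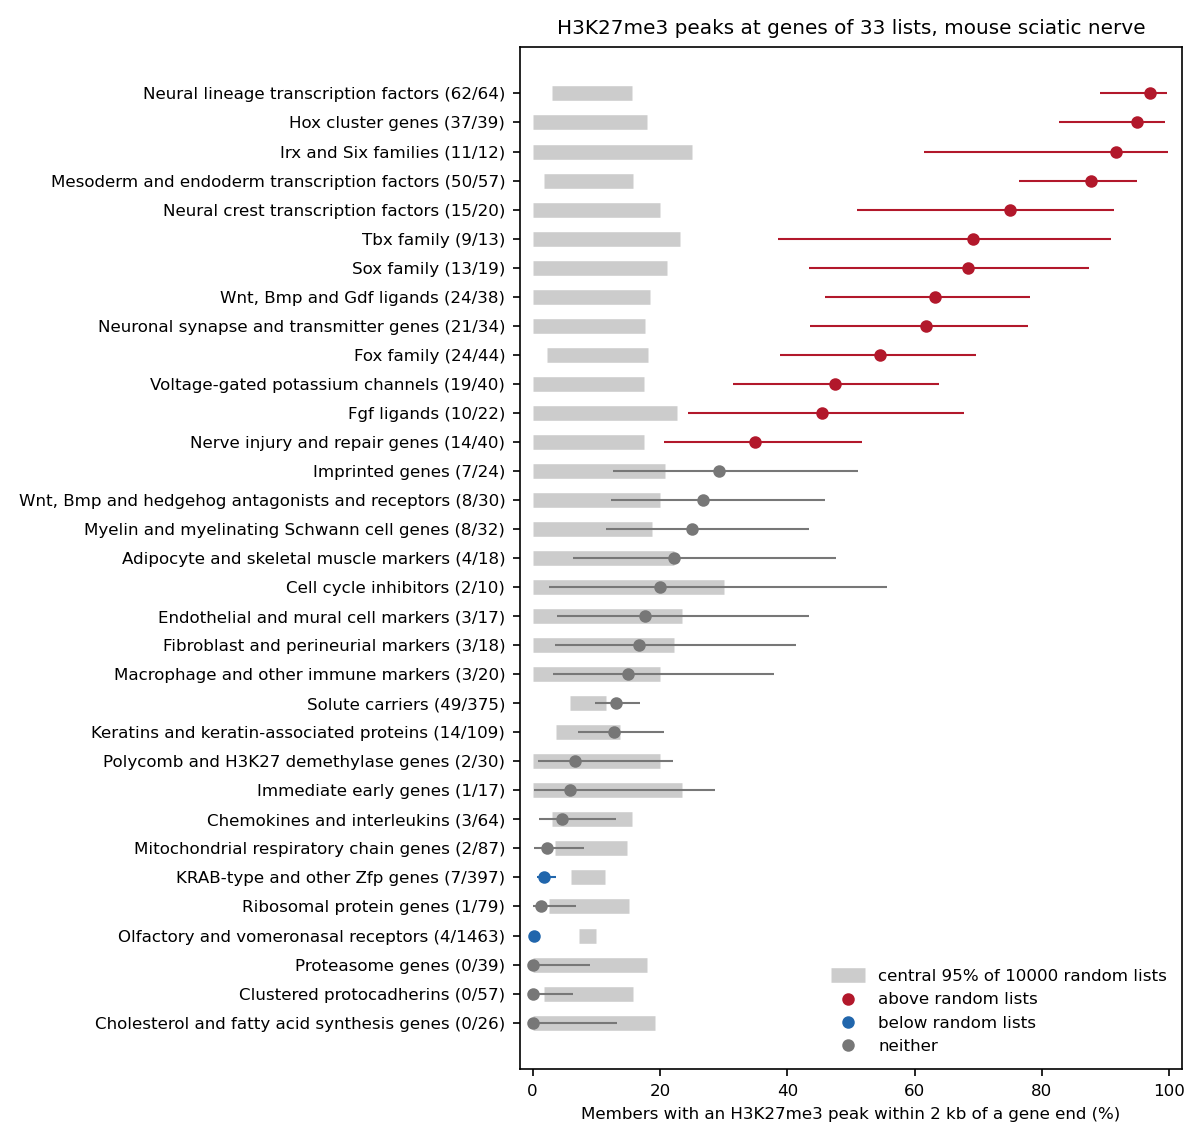
Share of each gene list with an H3K27me3 peak within 2 kb of a gene end (horizontal axis, %), with marked and measured members in brackets. Points are the observed shares, thin lines their exact 95% binomial intervals and grey bars the central 95% of 10000 random lists; 13 lists lie above random lists (red), 2 below (blue) and 18 neither (grey).

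All 4 Hox clusters carried the mark, and 37 of 39 Hox genes were marked (94.9%, 82.68 to 99.37; highest random list 11). The exceptions were Hoxc5 and Hoxc6, named after their values were seen. Peaks covered 52.3% of the Hoxd cluster (chromosome 2, 74666225 to 74767142), 43.3% of Hoxa (chromosome 6, 52153367 to 52262880), 37.0% of Hoxc (chromosome 15, 102919131 to 103038856) and 34.6% of Hoxb (chromosome 11, 96192316 to 96370254). Hoxb8 and Hoxd12 lay entirely within single peaks of 12394 and 14116 bp, and Hoxc13 touched one of 17477 bp. In a grouping made after seeing the data, the median share of the gene body covered was 31.65% for paralog groups 1 to 4, 59.1% for groups 5 to 9 and 89.95% for groups 10 to 13. Each group spanned a wide range, reaching 100% in all 3, and neighbouring genes share peaks, so this order was not tested.

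**Figure D2:**
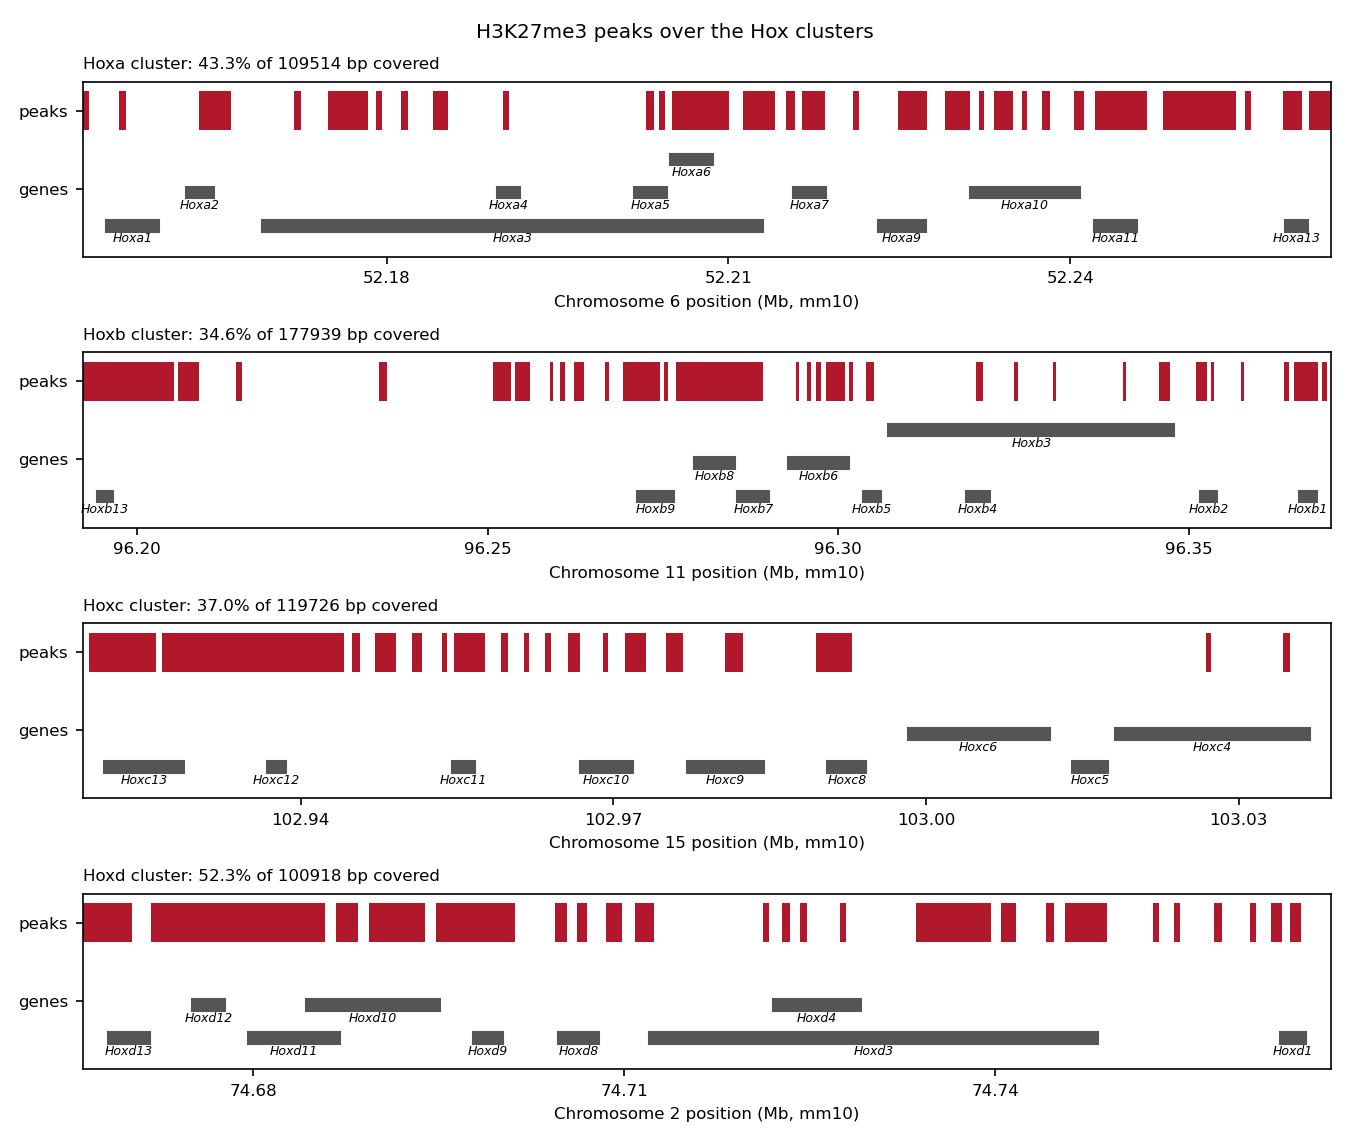
Peaks (red) and annotated Hox genes (grey) along the 4 Hox clusters, with position in Mb (mm10) on the horizontal axis; the vertical offset of genes has no meaning. Peaks cover 34.6% (Hoxb) to 52.3% (Hoxd) of a cluster, and Hoxc5 and Hoxc6 have no peak within 2 kb of an end.

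Genes linked to nerve injury and repair were marked more often than random lists of genes, a call that was lost without 7 genes put in the list from knowledge of Polycomb work in Schwann cells (8 of 33 marked, reached by 68 of 10000 random lists). Of 40 genes in this list, 14 were marked (35.0%, 20.63 to 51.68), against 3.4 in the average random list and 11 in the highest. Among them, Shh, Cdkn2a and Olig1 had the most reads in peaks that overlapped the windows at their ends, counting whole peaks. Shh, a morphogen, had 216 reads in 3 peaks, the widest 4714 bp (chromosome 5, 28457700 to 28462413). Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 regulator p19, had 196 reads in a peak of 8135 bp. Olig1, an oligodendrocyte lineage factor, had 104 reads, and 96.2% of the gene was covered. Trophic factors were among the marked genes. Near an end, Fgf5 had a peak of 2636 bp with 54 reads, Bdnf one of 1664 bp with 29 reads, Gdnf one of 1502 bp with 24 reads and Artn one of 1202 bp with 24 reads. Counted over the whole gene and its 2 kb flanks, Cdkn2a had 324 reads in 4 peaks, Bdnf 109 reads in 3 peaks and Gdnf 107 reads in 2 peaks. Hmga2 had 65 reads near its ends and 107 over the gene and flanks, and Sox2 had 49 in both counts.

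Other marked repair genes rested on few reads. Igfbp2 had 14 reads, Cdh2 12, Vegfa 11 and the neurotrophin receptor gene Ngfr 10, each in 1 peak near an end, and Ngfr had 20 reads in 2 peaks over the gene and flanks. Unmarked were Jun, the transcription factor that drives the repair state, and Atf3, Aspn, Bmp7, Btc, Ccl2, Clcf1 and Ednrb, none with a peak anywhere in the gene or its 2 kb flanks. Runx2, named after its value was seen, had a peak of 19 reads inside the gene and none near an end. The list is not independent evidence, because of those 7 genes, without which its share was 24.2%. It was also not called when at least 50% of a window had to be covered (10.0%).

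**Figure D3:**
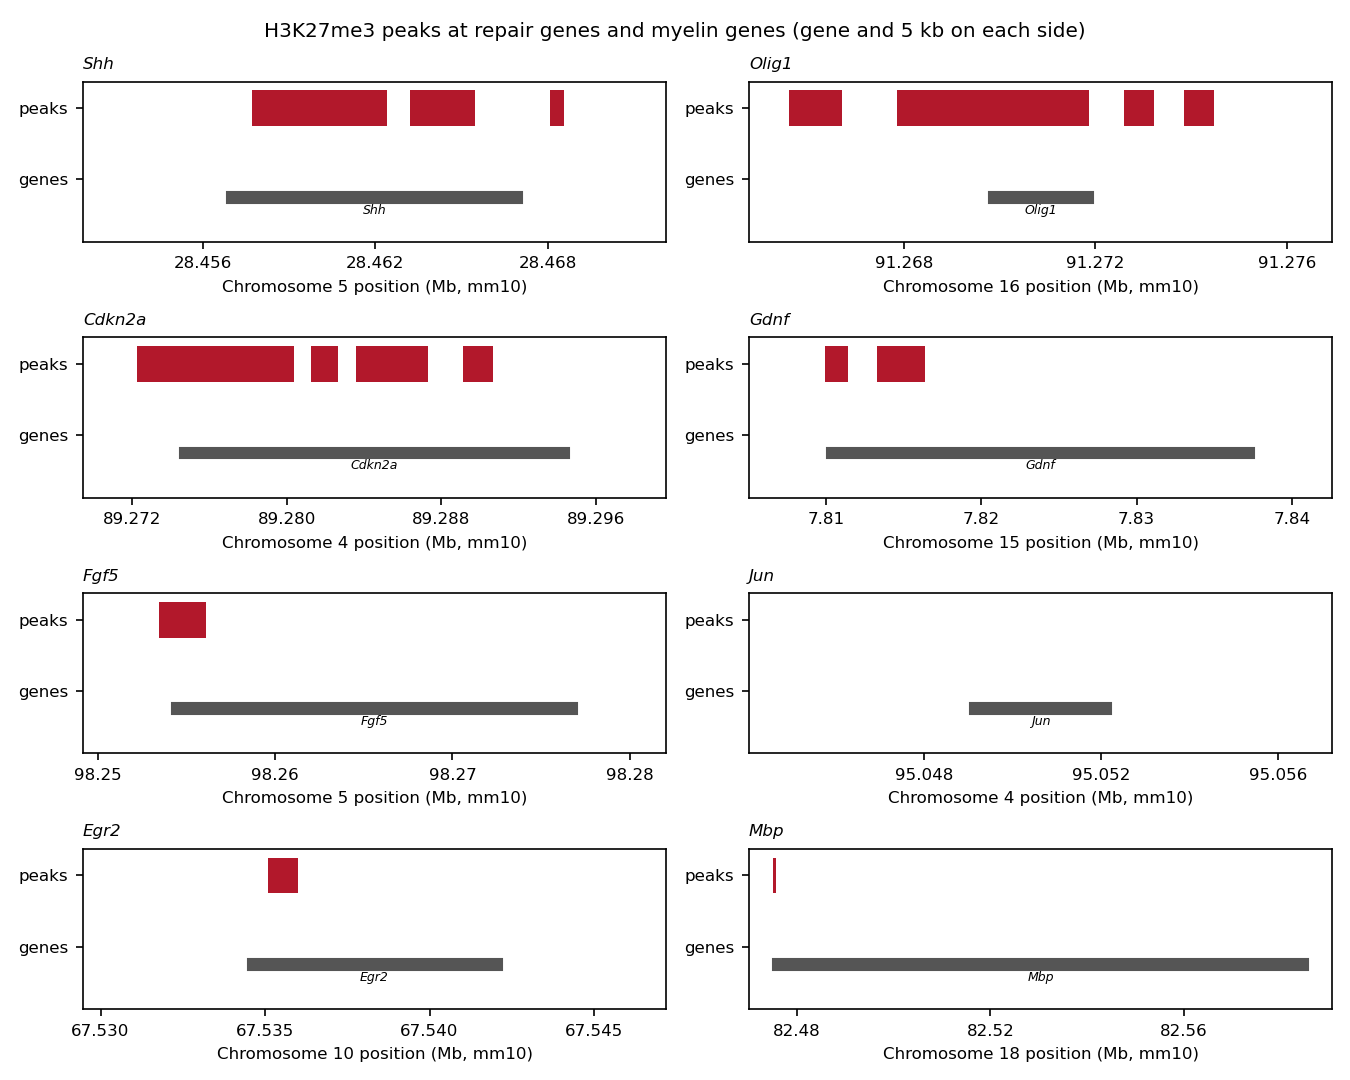
Peaks (red) and the annotated gene (grey) at 6 repair genes and 2 myelin genes, each with 5 kb on both sides and position in Mb (mm10) on the horizontal axis. Shh, Olig1, Cdkn2a, Gdnf and Fgf5 have peaks, Jun has none, and Egr2 and Mbp have a single peak of 18 and 11 reads.

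Most genes of the myelin programme, which Schwann cells of the adult nerve express, were unmarked, and the marked ones carried peaks with few reads. Of 32 genes, 8 were marked (25%, 11.46 to 43.4), against 2.72 in the average random list. The myelin list was not called above random lists, 47 of 10000 of which reached its count. The repair list without its 7 known genes was similar, with 8 of 33 marked (24.2%), a count that 68 of 10000 random lists reached. The share marked therefore does not set the myelin list apart from the repair list without those genes. The myelin list was called above circular shifts of the peaks, which marked 0.557 members on average. Protein-coding genes as a whole also exceeded the shifts, 4.5-fold, so that call does not set the myelin list apart from other genes. The marked myelin genes' median of 11 reads near gene ends compares with 28 for marked repair genes. The myelin protein gene Mbp had 11 reads, the myelin regulators Egr2 and Sox10 had 18 and 11, Nfasc 11 and Ugt8a 10. The only Mbp peak lay at an annotated end (chromosome 18, 82475087 to 82475586) and covered 0.449% of the gene. Which Mbp transcripts start there was not examined, as no transcript annotation was used. Ncmap with 22 reads and Dusp15 with 26 reads in 2 peaks had the most. Pmp22, Mag and Prx had no peak. With peaks of at least 20 reads, an alternative added after seeing the data, 3.12% of the list was marked. Of 26 cholesterol and fatty acid synthesis genes, which supply myelin lipids, 0 were marked, which allows a share of up to 11.5%.

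In each of 4 lists of markers of cell types other than Schwann cells, the share marked lay inside the central 95% range of random lists. The counts were 3 of 18 for fibroblast and perineurial cells (16.7%, 3.579 to 41.42), 3 of 17 for endothelial and mural cells (17.6%), 3 of 20 for macrophages and other immune cells (15%) and 4 of 18 for adipocytes and skeletal muscle (22.2%). Named after their values were seen, the strongest were Flt1 (81 reads), Acta1 (79 reads) and Sfrp2 (59 reads). With 17 to 20 genes per list, only large differences from random lists were detectable. Pooled, 13 of the 73 markers were marked (17.8%, 9.837 to 28.53), against 8.585% of all protein-coding genes.

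Synapse and transmitter genes of neurons, whose cell bodies lie outside the nerve, were marked more often than random lists. So were voltage-gated potassium channel genes, a list set by gene symbol and not by cell type. Of 34 synapse and transmitter genes, 21 were marked (61.8%, 43.56 to 77.83; highest random list 11). They included the vesicular transporter genes Slc32a1 (296 reads, widest peak 9144 bp), Slc17a7 (126 reads) and Slc18a3 (99 reads). Of 40 voltage-gated potassium channel genes, 19 were marked (47.5%), and those with the most covered bases, Kcna7, Kcnc1 and Kcnc4, had 72, 79 and 114 reads. That list was no longer called when at least 50% of a window had to be covered, with 5 of 40 marked.

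Genes of secreted developmental signals were marked more often than random lists. Of 38 Wnt, Bmp and Gdf ligand genes, 24 were marked (63.2%, 45.99 to 78.19), including Wnt1 (159 reads), Wnt3 (123 reads) and Gdf7 (105 reads). Of 22 Fgf genes, 10 were marked (45.5%), including Fgf8 (170 reads), Fgf3 and Fgf15. No random list reached either count. Wnt, Bmp and hedgehog antagonists and receptors had 8 of 30 marked (26.7%) and were not called, with 25 random lists reaching that count. They were called above circular shifts, which protein-coding genes as a whole also exceeded.

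Cell cycle inhibitor, Polycomb, imprinted and solute carrier genes were not called above or below random lists, though imprinted and solute carrier genes were called in some other settings. Of 10 cell cycle inhibitors, the marked ones were Cdkn2a and its neighbour Cdkn2b (20%, 2.521 to 55.61), the latter named after its value was seen. Of 30 Polycomb and H3K27 demethylase genes, Cbx8 and Bmi1 were marked (6.67%), both named after their values were seen, and the Bmi1 peak lay beyond the gene's end. Imprinted genes had 7 of 24 marked (29.2%, 12.62 to 51.09) and solute carriers 49 of 375 (13.1%), both outside the central 95% range of random lists (0 to 5 and 22 to 43). Imprinted genes were called above with the whole gene and its flanks (10 of 24) and with circular shifts. Solute carriers were called above with the 5 kb window (61 of 375), with the whole gene and its flanks (62 of 375) and with circular shifts. Protein-coding genes as a whole also exceeded circular shifts, 4.5-fold, so the calls against shifts do not set either list apart from other genes. Keratins and keratin-associated proteins had 14 of 109 marked (12.8%), within the range of random lists.

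Chemosensory receptor and zinc finger genes, many of which lie in large clusters, were marked less often than random lists. Of 1463 olfactory and vomeronasal receptor genes, 4 were marked (0.273%, 0.07454 to 0.6985), against 126 in the average random list. The mean was 48.8 with random lists matched on gene length and 23.3 with circular shifts, and the list was called below in both. Olfr94, Olfr222 and Olfr95 had the most covered bases. Of 397 Zfp genes, 7 were marked (1.76%, 0.7118 to 3.599), against 34.1, among them Zfp423, Zfp853 and Zfp488. Shifted peaks, which keep neighbouring genes together, marked 8.76 Zfp genes on average, and the Zfp list was not called below them. No clustered protocadherin gene of 57 was marked, which allows up to 5.26%. Of 10000 random lists, 50 had as few, and of those matched on gene length 9 did. The list was called below in the length-matched setting only. Circular shifts marked 0.811 of these genes on average, and 734 of 1000 shifts marked as few. Shifts also move peaks off gene ends, and marked 417.2 protein-coding genes on average against 1879 observed. Low shifted counts therefore arise for gene lists in general. The shifts do not show whether clustering of genes accounts for the low Zfp and protocadherin counts.

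Genes that most cells express were seldom marked, without reaching the limit for a call. The counts were 1 of 79 ribosomal protein genes (1.27%), 0 of 39 proteasome genes (up to 7.69% allowed) and 2 of 87 genes of the mitochondrial respiratory chain (2.3%). Immediate early genes had 1 of 17 marked (5.88%), which was Egr3 with 11 reads, named after its value was seen. Chemokines and interleukins had 3 of 64 marked (4.69%).

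The X chromosome carried far less of the mark than any autosome. Its 31 peaks (exact 95% Poisson interval 21.1 to 44.0) covered 0.0156% of its annotated span, against 0.311% over the 19 autosomes, a ratio of 0.0504. Single autosomes ranged from 0.131% (chromosome 16) to 0.635% (chromosome 19), with a mean of 0.315% ± 0.121 (SD over autosomes). Of 966 X-linked protein-coding genes, 14 were marked (1.45%), against 9.02% of autosomal genes. The Y chromosome had 1 peak. Males have a single X, so X-linked sequence is expected at a lower dose than autosomal sequence in both libraries.

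**Figure D4:**
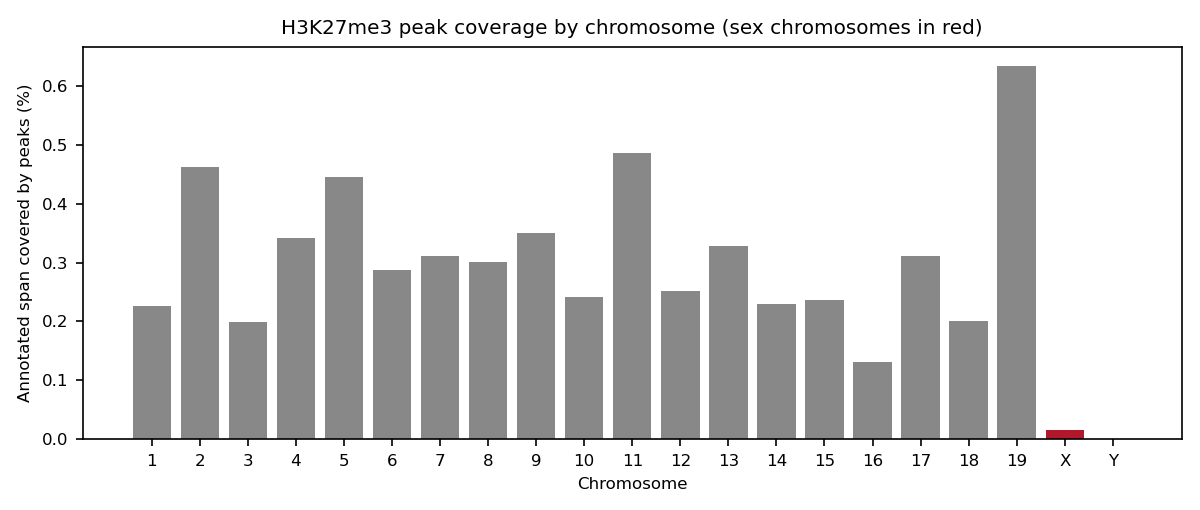
Percent of each chromosome's annotated span covered by H3K27me3 peaks (vertical axis) for the 19 autosomes (grey) and the sex chromosomes (red). X lies at 0.0156%, below the lowest autosome at 0.131%, and Y has 1 peak.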

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

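All tests of explanations in this part were chosen after the results they address had been seen, and so were the counts over non-coding genes.

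Peaks lay more often than shifted peaks at 3 of 7 gene types other than protein-coding, while the counts for pseudogenes, snRNA, snoRNA and V segment genes lay below the shifted means. Of 12727 long non-coding RNA genes, 804 had a peak within 2 kb of an end, against 228 on average over 100 shifts (central 95% range 200 to 260), and 293 of them lay over 5 kb from any protein-coding end. Of 1228 microRNA genes, 58 did, against 13.6 (5.47 to 26.5), and 28 of them lay over 5 kb from any protein-coding end. Of 408 transfer RNA genes, 59 did, against 4.54 (0 to 18.5), 50 of them over 5 kb from such an end, and the 59 fell in 20 domains, so the count rests on few places.

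Few peaks lay on the X chromosome. A single X copy in males could lower read numbers, but even the upper Poisson bound of all X peaks, 0.258 per Mb, lay below the 0.428 per Mb that peaks of at least 20 reads, which would keep 10 reads at a lower dose, had on the sparsest autosome, chromosome 16. Dose alone therefore does not account for the gap. A scarcity of developmental genes on X stays open. Outside all lists, 1.32% of X genes (12 of 909, 0.6839 to 2.295) were marked, against 4.27% of autosomal genes by peaks of at least 20 reads, but chromosome 16 had 2.22%, inside that interval.

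A set of 24 peaks held 5.77% of all reads in peaks, at over 52.42 reads per kb. Strong Polycomb sites at genes are argued against, since 4.17% of them (1 of 24, 0.1054 to 21.12) lay near a protein-coding gene end, against 57.8% of 1561 other peaks with as many reads, which are wider (median 2205 against 628.5 bp), and 39.8% of other peaks of matched width. Reads of repeated sequence could be a source. Of the 24, 1 overlaps annotated ribosomal RNA sequence (Rn18s-rs5), and 11 overlap no annotated gene of any type. Some lie close together, on chromosome 2 (98662257 to 98667502) and chromosome 9 (3000996 to 3025901). Whether these or the others hold repeated sequence cannot be told, because no genome sequence was searched.

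H3K27me3 is known as a mark of silent genes, yet 8 myelin genes were marked in a nerve that makes myelin. Chance placement of weak peaks is argued against, because 5 of the genes were marked by peaks of 11 reads or fewer, against a mean of 0.224 and a highest count of 2 over 1000 shifts. Whether a general tendency of weak peaks to lie at gene ends accounts for these 5 genes could not be decided. Such peaks marked 15.6% of the list, against 2.39% of all protein-coding genes. In random lists they marked 0.768 members on average, with a central range of 0 to 3, below the 5 observed. The limit for a call was missed, since 18 of 10000 random lists reached that count, above the limit of 10. Chromatin of cells that do not make myelin may contribute, as the nerve was unsorted. Of 73 markers of 4 other cell classes, 2 of them also in another list, 17.8% (13 genes, 9.837 to 28.53) were marked. The 73 include adipocyte and skeletal muscle markers, of which 4 of 18 were marked. The cells behind the myelin peaks cannot be told apart in 1 mixed library.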

How the results depend on the processing

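Depth and annotation limit these results, and the settings with peaks of at least 20 reads, without dense peaks and with each peak given to its nearest gene were chosen after seeing the data. The number of peaks was 3818 when merged within 5 kb, 3061 at or above the median score and 2125 with at least 20 reads. Marked genes fell to 466 when at least 50% of a window had to be covered and to 1036 with at least 20 reads. The lists below random lists went from 2 to 1 without receptor genes in the background, by construction, and to 1 with circular shifts, where the Zfp list was no longer called, and to 3 with random lists matched on gene length, where clustered protocadherins were gained. The repair list was no longer called at 50% of a window (10.0%) and without its 7 known genes (24.2%). The myelin list, at 25%, was called above circular shifts, which protein-coding genes as a whole also exceeded. Covered bases near gene ends were 23.5% with a 1 kb window, which follows from its size, and 42.0% for the peaks at or above the median score. The ratio of X to autosomes was 0.0741 by peaks per Mb. For the others the cause was not tested. Over 363 pairs of list and alternative, 351 kept their call, 4 lost it, 8 gained it (imprinted genes, solute carriers, antagonists and receptors, protocadherins and myelin genes) and 0 changed direction; 11 of the 13 lists above random lists stayed above in every alternative. No paired analysis was possible because each group has 1 library. Windows at every transcript start, lists matched on CpG content and the CpG alternatives were not run, as they need a transcript annotation or a genome sequence not used here.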

Other observations

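The search over gene families, made after seeing the data, covered 524 families with at least 6 members by symbol prefix, and 16 of them had more marked members than any of 10000 random lists. Of these, 2 had no member in the lists set beforehand, both receptors for transmitters. Of 6 adrenergic alpha receptor genes (Adra), 5 were marked (83.3%), and Adra2c, with 96 reads, was covered over 92.8% of its length. Of 14 serotonin receptor genes (Htr), 7 were marked (50.0%), among them Htr1a with 33 reads. The Pax, Lhx and Dlx families were marked in full, with 9 of 9, 8 of 8 and 6 of 6 members.

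Among imprinted genes, which are expressed from 1 parental copy, Dio3 had 112 reads near its ends and Dlk1 had 53, both on chromosome 12. Zdbf2 had no peak near its ends but held a domain of 39686 bp inside the gene (chromosome 1, 63243392 to 63283077), with 340 reads in 11 peaks. These genes were named after their values were seen. Pseudogenes were marked less often than by shifted peaks, at 74 of 9944 against 119 (central 95% range 101 to 143).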
